A study of Arabidopsis thaliana with 12 samples.

How the data were processed

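Gene expression was measured in roots of 7-day-old Arabidopsis thaliana seedlings of the ecotype Col-0 after 25 min with an elicitor or with no elicitor. Plants grew on nylon mesh that let roots be separated from shoots, and total RNA from roots was hybridized to Affymetrix ATH1 GeneChips, short-oligonucleotide arrays on which a gene is read by a probe set. There were 12 arrays in 4 groups of 3 biological replicates, namely control, cellobiose, chitin and oligogalacturonides (OGs). The labels call the chitin treatment chitin, and the design text of the series calls it chito-oligomers. Doses are not given in the sources used here. The design text also speaks of another time point, which was not analysed here.

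The values are log2 probe set intensities that the authors normalized with GCRMA (background correction by probe sequence, quantile normalization and median polish), per the series' design text. Per the submitters' processing notes, Affymetrix Expression Console was also named, without a version or a role. Scanner files were not used here. The deposited table holds 22810 rows. Of these, 64 are Affymetrix control probe sets, which were kept apart, and 22746 were tested. The array medians lay close together, as a between-array normalization gives, so a shift that all genes shared would not be visible in these values. Arrays carry no sequencing depth, and their number limits the precision.

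Probe sets were named through GEO's platform annotation, with symbols and synonyms updated by locus through the RefSeq annotation of TAIR10.1 (used for names and for which genes neighbour each other). That annotation lists 14016 of the probe sets: 13513 with 1 gene, which is 59.4% of those tested, and 503 with several, which were not named. The other 8730 are unnamed here and appear by probe set ID. Of probe sets with 1 gene, 1580 carry a symbol other than the locus identifier, and 13436 matched the RefSeq annotation. The level of WRKY30, which the submitters used to screen the RNA samples by qRT-PCR, was not analysed here because no table used here names a probe set for it. What that screen does to the counts, sizes and likeness of the responses was not tested.

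Differential expression was tested with limma 3.58.1 in R 4.3.3. One linear model held treatment with 4 levels and the replicate number as a block, fitted to all 12 arrays with eBayes at its default settings, which left 6 residual and 3.09 prior degrees of freedom. The block was used because the design text takes elicitor to control ratios per sample pair. Tests were two-sided, and p was adjusted by Benjamini-Hochberg over the 22746 probe sets within a comparison. A probe set was called at an adjusted p under 0.05. Standard errors (SE) and 95% intervals come from the same fit. A log2 fold change is the mean of the 3 pairwise log2 ratios.

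Before the data were examined, 23 gene lists with 334 distinct genes were fixed, together with the comparisons, the alternatives and a rule for the genes to name. The rule took, per elicitor, the 10 largest rises and 6 largest falls among called probe sets of 1 gene with a symbol that moved the same way in all 3 pairs, and up to 2 called members per list with the smallest p. Between elicitors it took the 6 largest differences in each direction. Only 47 of the listed genes had a named probe set, and 7 lists had at least 3 of them, a minimum that was set after the data were seen. Such genes are called measured below. The other listed genes may be read by probe sets that are unnamed here. Those 7 lists were tested with camera at a preset correlation of 0.01 over 13333 genes, with the brightest probe set standing for each gene, and p was adjusted over 21 tests. Camera with an estimated correlation and fry were run beside it.

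Since the elicitor comparisons share their control arrays, 100 data sets of unchanged groups that share controls were simulated with the fitted spread. The 3 control arrays were not split between the comparisons. Response size was the mean over called probe sets of the log2 ratio to the control mean, with the sign of each probe set's change, computed per array on the probe sets called with the remaining elicitor. It was compared by a two-sided exact permutation test, whose smallest p is 0.1 for 3 arrays against 3. This measure, gene families formed from symbols, counts of neighbouring genes and a scaling to the poly-A spike-ins (24 probe sets for RNAs added to each sample) were added after the data had been seen. On the scaled values limma estimated infinite prior degrees of freedom, which gives every probe set the same variance (0.0885), so its p values were not used. Ordinary t tests with 6 degrees of freedom were run instead on scaled and unscaled values, also chosen after the data had been seen, and camera on their z scores.

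The scripts were tested on simulated data. In a simulated cellobiose comparison over 22746 probe sets, 200 were shifted in 4 classes of 50. Changes of 0.5, 1, 2 and 3 log2 were called for 30%, 84%, 98% and 100% of their class, and 11 of 167 calls were false. Of 200 unshifted lists of 4 genes, 4.5% had a camera p under 0.05, and 20 of 20 lists shifted by 2 log2 passed in the right direction. The simulated genes varied independently of each other, whereas the estimated correlation of the tested lists reached 0.89 (pectin genes). The simulation therefore does not show how camera at the preset correlation behaves on correlated lists.

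The alternatives were a fit with no replicate block, replicate number as a random block, only the 2 groups compared, a trended and robust prior, bright probe sets only, quantile normalization, median centring, a 2-fold minimum, a mean ratio with no test, ordinary t tests with and without the spike-in scaling, and each replicate number or array left out. No detection calls were used, so no probe set was shown to be above background.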

Results

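Plants detect fragments of cell walls as signs of damage or attack. The study asked how roots respond within 25 min to 3 such oligosaccharides: cellobiose, a disaccharide of glucose from cellulose; chito-oligomers (here chitin), chains of N-acetylglucosamine from fungal walls; and OGs, chains of galacturonic acid from pectin. Expression of 22746 probe sets was read on 3 arrays for each elicitor and on 3 control arrays. Array medians averaged 6.57 on the log2 scale in controls and 6.55 over the elicitor arrays, and values ran from 2.77 to 14.57. Replicate arrays correlated at 0.986 to 0.996 across probe sets in the control group and at 0.986 to 0.993 in the elicitor groups. The first principal component held 53.6% of the variance, and all 9 elicitor arrays lay beyond the controls on it. Control replicate 1 lay nearest to them at -34.4, against -61.9 and -64.1 for the other controls, and OGs replicate 2 was the closest elicitor array at -13.4.

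To find which genes cellobiose changed, its arrays were set against the controls. WRKY53, a transcription factor of defence and senescence, rose 66.6-fold, from 6.62 ± 0.68 to 12.68 ± 0.13 on the log2 scale (SD, n = 3; adjusted p = 2.2e-05). DLAH, a lipase, rose 42.4-fold, CCR2, a cinnamoyl-CoA reductase of lignin synthesis, 20-fold, and the calmodulin-like gene CML37 18.5-fold. WRKY22 rose 14.0-fold, the expansin-like gene EXLA3 12.7-fold, the tetraspanin gene TET9 11.2-fold, and PUB24, a ubiquitin ligase that restrains immune signalling, 9.81-fold. STZ, a zinc finger repressor of stress responses, rose by 3.18 ± 0.66 log2 (SE). BGLU27, a member of the beta-glucosidase family, rose from 3.91 ± 0.11 to 7.14 ± 0.55 (SD, n = 3; adjusted p = 5.7e-05), and its control level was not shown to be above background. Without control replicate 1 the log2 changes of CML37, EXLA3 and STZ were 4.86, 4.61 and 4.17, against 4.21, 3.67 and 3.18 with it, and STZ was at 2.57 without control replicate 3.

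Among the falls with cellobiose, LEA4-5, a late embryogenesis abundant protein linked to water stress, fell by 2.59 ± 0.53 log2 (SE). The RING-type ubiquitin ligase gene ATL8 fell by 1.67 ± 0.25, the U-box ligase gene PUB19 by 1.54 ± 0.40, SIS by 1.52 ± 0.30, SIM, a cyclin-dependent kinase inhibitor that promotes endoreduplication, by 1.39 ± 0.21, and CCL by 1.38 ± 0.29. LEA4-5 fell by 3.25 without cellobiose replicate 3, and PUB19 fell by 0.93 without cellobiose replicate 2 and had an adjusted p of 0.0993 with no replicate block. In all, 1077 probe sets rose and 889 fell (limma, adjusted p under 0.05), of which 660 and 131 changed at least 2-fold. All 1966 moved the same way in 3 of 3 pairs. With ordinary t tests 632 were higher and 374 lower, and after scaling to the poly-A spike-ins, which put the median of all probe sets at 0.34 log2, 932 were higher and 6 lower. SIM then did not pass (adjusted p = 0.216), at -1.01 ± 0.35 log2 (SE) against -1.39 ± 0.25 in the unscaled ordinary t test. The count was 773 without control replicate 3 and 853 without cellobiose replicate 1. Of 24 named genes, 18 kept their call whichever array was left out, and STZ, LEA4-5, PUB19, SIS, CCL and AT2G28200 did not; these 6 and AT4G20860 did not pass ordinary t tests either.

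The same question was put to chitin. WRKY53 rose 78.1-fold, from 6.62 ± 0.68 to 12.91 ± 0.18 (SD, n = 3; adjusted p = 2.1e-05), and CML37 rose 47.7-fold. DLAH rose 38.0-fold, and GLR2.8, a glutamate receptor-like channel gene, rose from 4.13 ± 0.27 to 8.49 ± 0.82 (SD, n = 3; adjusted p = 0.0031). STZ rose 15.9-fold, WRKY22 14.8-fold, CCR2 13.2-fold, TET9 10.7-fold, AR781 9.78-fold and PUB24 8.88-fold. GRX480, a glutaredoxin induced by salicylate, rose by 2.57 ± 0.45 log2 (SE), and its adjusted p was 0.188 with no replicate block. CML37 had a log2 change of 5.58, and 6.23 without control replicate 1 and 4.81 without chitin replicate 2. GLR2.8 was at 3.72 rather than 4.36 without chitin replicate 2, and STZ at 4.97 and 3.37 rather than 3.99 without control replicates 1 and 3.

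With chitin, LEA4-5 fell by 2.09 ± 0.53 log2 (SE), ATL8 fell by 1.86 ± 0.25, SIM fell by 1.64 ± 0.21 and SIS fell by 1.38 ± 0.30. The tetraspanin gene TET5 fell by 1.16 ± 0.13, and XERICO, a RING protein linked to abscisic acid, fell by 1.04 ± 0.17. HCT, an acyltransferase of lignin synthesis, fell by 0.35 ± 0.08. SIM, TET5, XERICO and HCT passed ordinary t tests as deposited but not after spike-in scaling (adjusted p = 0.136, 0.122, 0.411 and 0.807). Their changes in these tests went from -1.64 ± 0.25, -1.16 ± 0.14, -1.04 ± 0.19 and -0.35 ± 0.06 to -1.43 ± 0.35, -0.95 ± 0.23, -0.83 ± 0.31 and -0.14 ± 0.19 log2 (SE). In all, 1130 probe sets rose and 872 fell, of which 708 and 147 changed at least 2-fold, and all 2002 moved the same way in 3 of 3 pairs. With ordinary t tests 743 were higher and 368 lower, and 715 and 15 after spike-in scaling. The count was 1221 without control replicate 2, 879 without control replicate 3, 980 without chitin replicate 2 and 1232 without chitin replicate 3. LEA4-5 and HCT lost their call whichever of the 6 control and chitin arrays was left out. SIS lost its call without 4 of the 6, and GRX480 without control replicate 3. With no replicate block LEA4-5 also lost its call (adjusted p = 0.0704). Ordinary t tests kept 21 of 26 named genes and lost LEA4-5, SIS, STZ, GRX480 and ATPMEPCRB.

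With OGs, WRKY53 had the largest rise among genes with a symbol, 38.6-fold to 11.89 ± 0.27 (SD, n = 3; adjusted p = 1.1e-04). DLAH rose 10.5-fold, WRKY22 6.41-fold, the caffeoyl-CoA methyltransferase gene CCOAMT 6.15-fold, CCR2 5.68-fold, AR781 5.06-fold, PUB24 4.60-fold, the related ligase gene PUB23 4.50-fold, TET9 4.14-fold and the RING ligase gene RING1 3.80-fold. CML37 was 5.74-fold higher, but did not pass (adjusted p = 0.070). LEA4-5 fell from 8.86 ± 0.41 to 6.26 ± 1.43 (SD, n = 3; adjusted p = 0.028). In log2 terms (with SE) SIS fell by 1.40 ± 0.30, the trihelix factor gene GT2 by 0.82 ± 0.16, CPUORF47 by 0.71 ± 0.15, bZIP58 by 0.67 ± 0.13 and the glycosyltransferase gene UGT71C4 by 0.63 ± 0.11. AR781 (adjusted p = 0.0542) and bZIP58 (0.0523) did not pass with no replicate block. The log2 change of CCOAMT was 1.79 rather than 2.62 and LEA4-5 fell by 1.88 without OGs replicate 3, and CCR2 was at 3.32 rather than 2.51 without OGs replicate 2.

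OGs raised 723 probe sets and lowered 201, with 457 and 52 of them changed at least 2-fold, and all 924 moved the same way in 3 of 3 pairs. With ordinary t tests 70 were higher and 9 lower, and 296 and 0 after spike-in scaling. The count was 146 when only OGs and control arrays were fitted, and 310, 207, 484 and 390 without control replicate 2, control replicate 3, OGs replicate 1 and OGs replicate 3. Of 24 named genes, 9 kept their call whichever array was left out, but ordinary t tests kept only WRKY53, PUB24, WRKY6 and AT4G20830 and lost the other 20, including DLAH (adjusted p = 0.0735) and WRKY22 (0.0755).

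Gene groups fixed in advance were then compared across the elicitors. Most list members had no named probe set and were not examined. Measured were 3 of 27 WRKY genes, 4 of 20 early immunity markers, 9 of 18 calcium genes and 3 of 10 pectin genes. Of the other tested lists, 3 of 19 phenylpropanoid, 6 of 18 auxin and 3 of 8 reference genes were measured. All 3 measured members of the WRKY list (WRKY53, WRKY22 and WRKY6) rose with every elicitor, over all genes and adjusted over the list alone. The list shifted up with cellobiose (camera adjusted p = 9.14e-09), chitin (1.80e-08) and OGs (9.14e-09), with adjusted p = 0.0263 with an estimated correlation in each. The other WRKY genes with a named probe set, WRKY20, WRKY42, WRKY47 and ZAP1, were not in the list and passed with no elicitor. All 7 as a family had an adjusted p of 0.681 with an estimated correlation. With OGs WRKY22 did not pass an ordinary t test (adjusted p = 0.0755). WRKY6 rose by 1.41, 1.69 and 0.99 ± 0.11 log2 (SE) with cellobiose, chitin and OGs, and with OGs did not pass an ordinary t test after spike-in scaling (adjusted p = 0.074), where it was at 1.21 ± 0.22 against 0.99 ± 0.12 unscaled. Of early immunity markers, 4 of 4 measured rose with every elicitor, by both adjustments. PUB22 rose by 2.37, 2.68 and 1.80 ± 0.28 log2 and PUB23 by 3.08, 2.92 and 2.17 ± 0.32. BIK1, a receptor-associated kinase, rose by 1.40, 1.17 and 1.21 ± 0.14. With ordinary t tests 4, 4 and 1 of them passed, the last being PUB24, while with OGs PUB23 (adjusted p = 0.0816), BIK1 (0.0527) and PUB22 did not. Camera gave adjusted p = 3.38e-09, 1.11e-08 and 3.38e-09, and adjusted p = 0.0505 with an estimated correlation each time.

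Of 9 measured calcium sensors and pumps, 5 rose with cellobiose, 5 with chitin and 4 with OGs, and 6 with each when adjusted over the list alone. AT5G39670, an EF-hand protein gene, rose by 5.10, 5.38 and 4.66 ± 0.56 log2 (SE), and CML42 by 2.88, 2.75 and 1.86 ± 0.23. Without control replicate 1 AT5G39670 was at 5.98, 6.26 and 5.54. With ordinary t tests 5, 5 and 0 of the list passed. The list shifted up (camera adjusted p = 2.14e-08, 2.12e-08 and 1.80e-08; adjusted p = 0.0505 with an estimated correlation). Of pectin and wall oligosaccharide genes, 3 of 3 measured rose with every elicitor by both adjustments. AT4G20830, which encodes an oxidase of OGs, rose by 2.31, 2.18 and 2.03 ± 0.21 log2, and AT4G20860, which encodes an oxidase of cellulose fragments, by 1.35, 1.01 and 1.56 ± 0.24. ATPMEPCRB, a pectin methylesterase gene, rose by 1.44, 2.03 and 1.74 ± 0.35. Only AT4G20830 passed ordinary t tests, with each elicitor. Camera adjusted p was 1.53e-05 with cellobiose, 4.35e-05 with chitin and 8.79e-07 with OGs, and adjusted p = 0.0673, 0.0755 and 0.0505 with an estimated correlation.

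**Figure D1:**
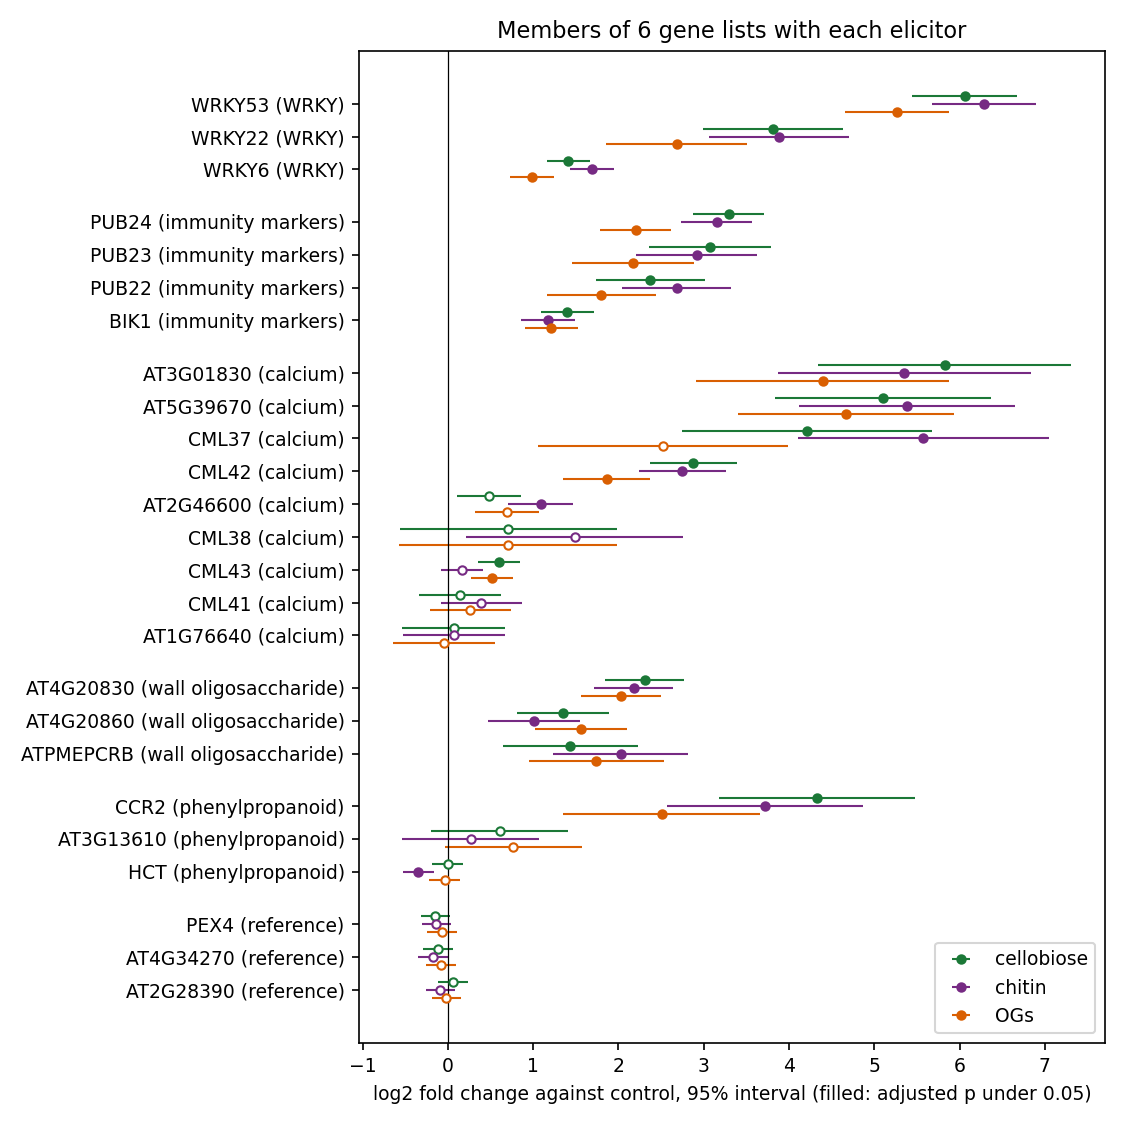
Log2 fold change against control (x axis) with its 95% interval for members of 6 gene lists (y axis), for cellobiose, chitin and OGs, from 3 arrays per group; filled points had an adjusted p under 0.05. WRKY53 sits furthest right, at 6.06, 6.29 and 5.27, and the 3 reference genes lie between -0.18 and 0.06.

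Phenylpropanoid synthesis had camera adjusted p = 0.0257 with cellobiose (upward; adjusted p = 0.0846 with an estimated correlation), 0.576 with chitin and 0.0501 with OGs (0.0397 with no replicate block). The elicitors were not compared on this list. Of its 3 measured members CCR2 rose with all elicitors (with OGs not in an ordinary t test, adjusted p = 0.152). HCT fell with chitin, a call lost whichever array was left out. AT3G13610 passed with none, by either adjustment. No member of the auxin list (6 measured) passed in any comparison by either adjustment, and camera gave adjusted p = 0.630, 0.913 and 0.711 with cellobiose, chitin and OGs. The auxin list's test pointed up with cellobiose and chitin while its medians were -0.04 and -0.07 log2, and with chitin its mean was -0.02. The 3 measured reference genes, PEX4, AT4G34270 and AT2G28390, passed in no comparison by either adjustment (camera adjusted p = 0.619, 0.204 and 0.591).

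The remaining lists had too few measured members to test as groups. Of zinc finger regulators, STZ rose with cellobiose and chitin and AT2G28200 fell with every elicitor, by 1.40, 1.77 and 1.36 ± 0.28 log2 (SE); adjusted over the list alone STZ also passed with OGs. Its calls with cellobiose (adjusted p = 0.0516) and OGs (0.0896) ended with no replicate block for AT2G28200, and its call with chitin ended after spike-in scaling (adjusted p = 0.152), at -1.56 ± 0.40 log2 (SE) against -1.77 ± 0.34 in the unscaled ordinary t test. Of salicylate genes, SAG101 rose with every elicitor, by 1.16, 1.43 and 1.03 ± 0.19 log2, and GRX480 rose with chitin; both passed with each elicitor when adjusted over the list alone. SAG101 with OGs (adjusted p = 0.123) and GRX480 (0.0586) did not pass ordinary t tests. No measured member, in brackets, passed over all genes in the lists of AP2/ERF factors (ORA47), immune receptors and kinases (EFR) and cellulose synthesis (COB). The same held for indole glucosinolate and camalexin synthesis (UGT74B1), chitinases (CHI, ChiC), sugar starvation (AKINBETA1) and heat shock (AT5G48570). It also held for the circadian clock (GI), shoot markers (RCA) and root hair markers (EXPA7, EXPA18). Adjusted over the list alone, where each is the only measured member, AKINBETA1 was lower with cellobiose and chitin and AT5G48570 higher with OGs. GI was then lower with OGs and RCA lower with cellobiose (-0.97 ± 0.34 log2, SE). None of the jasmonate, ethylene, endodermis and root cap, or vascular lists had a member with a named probe set. Whether their genes changed was not examined.

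How far the responses resembled each other was examined next. Of the probe sets changed with any elicitor, 2580 in all, 641 rose and 148 fell with all 3, and none changed in opposite directions. WRKY53, WRKY22, DLAH, CCR2, TET9 and PUB24 were among the shared rises, and LEA4-5 and SIS among the shared falls. Without some single arrays LEA4-5 and SIS lost their call with each elicitor, and CCR2 and TET9 with OGs. Cellobiose and chitin shared 906 rises and 538 falls, against 53.5 and 34.1 for independent lists. Cellobiose and OGs shared 663 and 166 (34.2 and 7.86 for independent lists), and chitin and OGs 666 and 162 (35.9 and 7.71). Fold changes correlated across probe sets at 0.925 for cellobiose and chitin, 0.923 for cellobiose and OGs and 0.916 for chitin and OGs, where unchanged groups sharing controls gave 0.5 on average. The covariances were 0.257, 0.196 and 0.205, against 0.012 in the simulation. Part of the excess may come from the shared controls, and genes are not independent replicates.

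**Figure D2:**
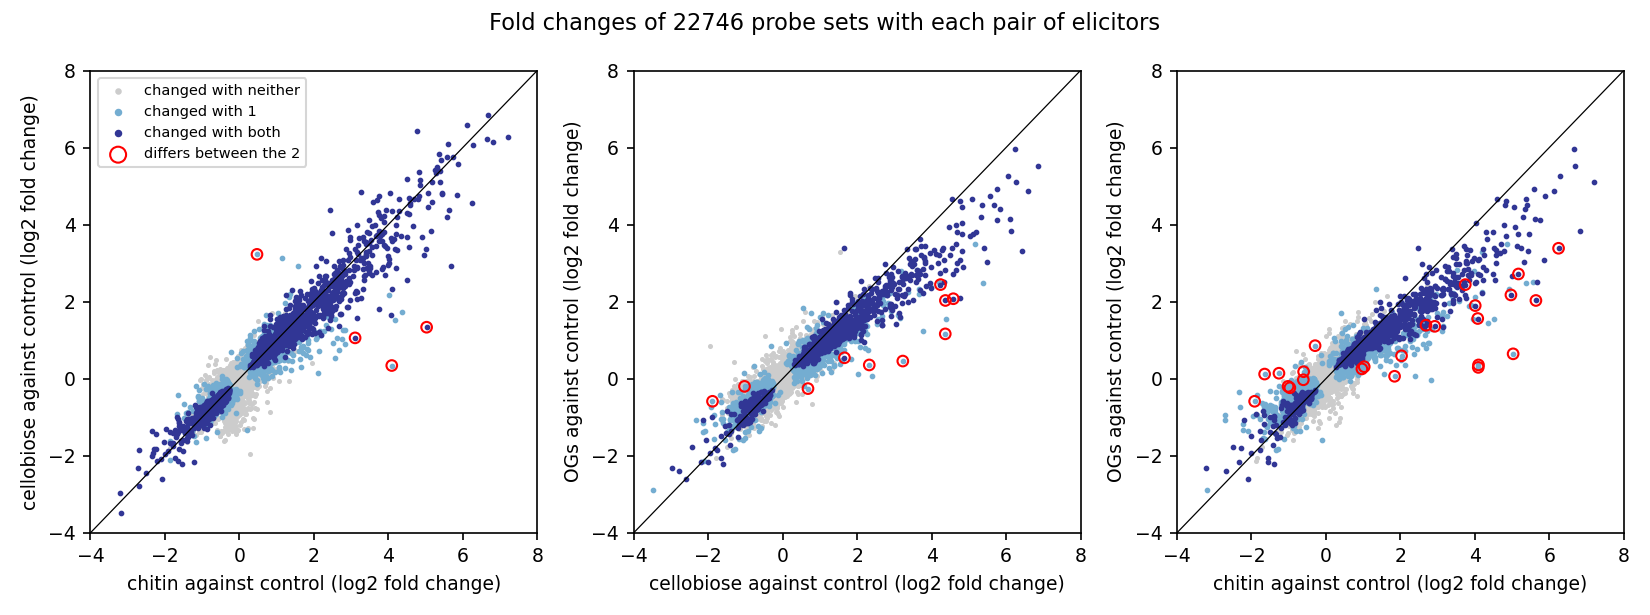
Log2 fold change against control with 1 elicitor (x axis) and another (y axis) for 22746 probe sets, coloured by whether 0, 1 or both changes passed; red circles mark probe sets that differed between the 2 elicitors, 4, 10 and 24 from left to right. Points follow the diagonal for cellobiose and chitin and lie on the chitin or cellobiose side of it where OGs are on the y axis.

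The elicitors were then compared directly. Their doses are not given in the sources used here, so matched doses cannot be assumed. Between the glucose disaccharide and the chito-oligomers, 4 probe sets differed (limma; 1291 at an unadjusted p under 0.05). BGLU27 was higher with cellobiose by 2.75 log2 (95% interval 2.32 to 3.19; adjusted p = 0.0017), at 7.14 ± 0.55 with cellobiose and 4.38 ± 0.08 with chitin (SD, n = 3). The locus AT3G12910 was higher with chitin, at 8.44 ± 0.78 against 4.75 ± 0.29, a difference of -3.69 for cellobiose minus chitin (interval -4.23 to -3.15; adjusted p = 0.0017). AT2G36440 was likewise at 7.78 ± 0.79 with chitin and 4.03 ± 0.33 with cellobiose (difference -3.75, interval -4.55 to -2.95; adjusted p = 0.015). The last was a probe set with no listed gene, at -2.05 log2. WRKY53 did not differ detectably (cellobiose minus chitin -0.23, interval -0.84 to 0.38), nor did PUB24 (0.14, interval -0.27 to 0.56) or AT4G20830 (0.13, interval -0.34 to 0.59).

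Cellobiose and OGs differed at 10 probe sets, 8 of them higher with cellobiose (1237 at an unadjusted p under 0.05), and at 19 with no replicate block. Without replicate 2 there were 86, of which 8 were higher and 78 lower with cellobiose, so no direction of the count was read. BGLU27 was again higher with cellobiose, by 2.77 log2 (interval 2.33 to 3.20; adjusted p = 0.0033). AT1G78410 was higher by 2.51 and AT3G20340 lower by 1.30 (difference -1.30, interval -1.66 to -0.93; adjusted p = 0.049). With quantile normalization neither passed (limma adjusted p = 0.0582 for each), and AT3G20340 lost its call whichever array was left out. The others named by the rule had no listed gene, and the largest of their differences was 3.20 log2. AT4G20830 differed by 0.28 (interval -0.19 to 0.74) and BIK1 by 0.18 (interval -0.13 to 0.50), neither of which passed.

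Chitin and OGs differed at 24 probe sets, 16 higher and 8 lower with chitin (1447 at an unadjusted p under 0.05). AT3G12910 was higher with chitin by 4.38 log2 (interval 3.84 to 4.92; adjusted p = 3.9e-04), AT2G36440 by 3.80 (interval 3.00 to 4.60; adjusted p = 0.0081) and AT1G07160, a protein phosphatase gene, by 2.86 (interval 2.15 to 3.58; adjusted p = 0.030). Probe sets with no listed gene were also higher, the largest by 3.74. AT3G20340 and AT3G15630 were lower with chitin than with OGs, with differences of -1.33 and -0.78, and AT3G15630 did not pass with no replicate block (adjusted p = 0.194). BGLU27 differed by 0.01 between chitin and OGs (interval -0.42 to 0.45). GLR2.8, called against control with chitin only, did not pass against OGs (chitin minus OGs 2.91, interval 1.45 to 4.37, adjusted p = 0.21) or cellobiose (cellobiose minus chitin -2.63, interval -4.09 to -1.17, adjusted p = 0.62).

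Across all probe sets the interval of the difference lay within 1 log2 of 0 for 95.6% between cellobiose and chitin, 95.5% between cellobiose and OGs and 95.1% between chitin and OGs. Among the 789 probe sets that changed with all elicitors these shares were 77.2%, 69.1% and 64.1%. BGLU27 kept its differences, and AT3G12910 both of its own, whichever array was left out, whereas AT2G36440 lost the call against cellobiose without cellobiose replicate 2 or 3 and against OGs without OGs replicate 1 or 2. Of the named differences, 2 of 4, 1 of 8 and 2 of 12 kept their call whichever array was left out. Single arrays left out gave 2 calls for cellobiose and chitin (without cellobiose replicate 3). For cellobiose and OGs there was 1 call without any cellobiose array or OGs replicate 1 or 2, and 29 without OGs replicate 3. For chitin and OGs there were 5 and 4 without chitin replicates 2 and 3, and 2, 4 and 105 without OGs replicates 1, 2 and 3. When only the 2 groups were fitted, none of these comparisons gave a limma call, and ordinary t tests on all arrays gave 0, 0 and 1, the 1 not among the 24.

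**Figure D3:**
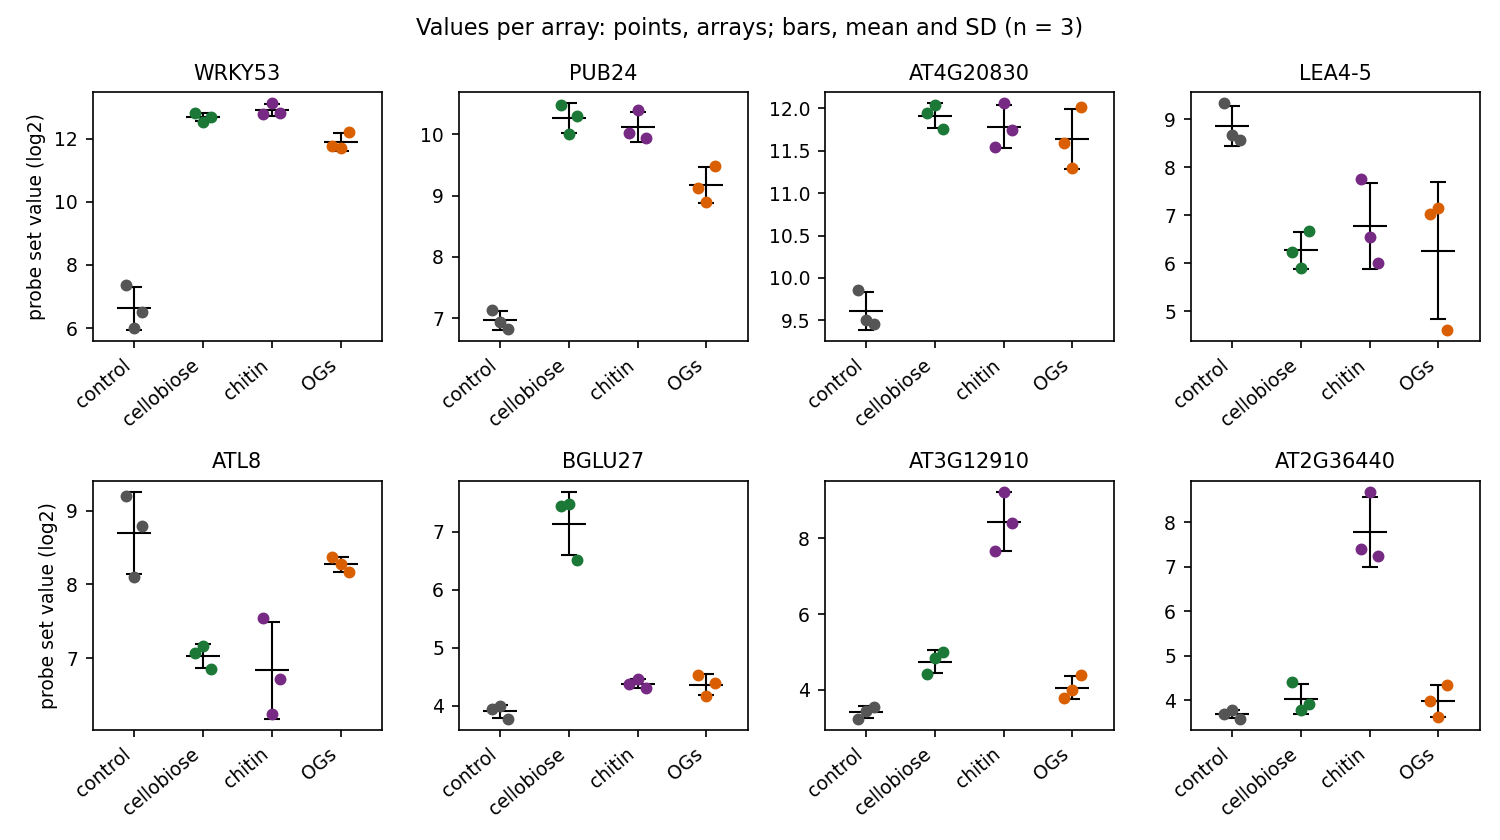
Log2 probe set value (y axis) of 8 genes on each of 12 arrays by group (x axis); points are arrays, and bars show the mean and SD (n = 3). BGLU27 stands at 6.51 or above on the cellobiose arrays and at 4.53 or below elsewhere, and AT3G12910 and AT2G36440 stand apart on the chitin arrays in the same way.

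The size of the response was compared on probe sets called with the remaining elicitor. Over 1966 probe sets changed by cellobiose, the mean change was 1.18 ± 0.07 log2 with chitin and 0.878 ± 0.207 with OGs (SD, n = 3; exact permutation p = 0.1, the smallest possible). Over the 2002 changed by chitin, it was 1.13 ± 0.16 with cellobiose and 0.882 ± 0.221 with OGs (exact permutation p = 0.3). Over the 924 changed by OGs, it was 1.60 ± 0.15 with cellobiose and 1.66 ± 0.13 with chitin (exact permutation p = 0.6). OGs replicate 2 had the smallest of the array values, 0.649 over the cellobiose set and 0.646 over the chitin set. Without it the differences from chitin and cellobiose were 0.186 and 0.134, and OGs had 1369 called probe sets.

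The poly-A spike-in probe sets, which read RNA added to the samples, averaged 6.96 ± 0.28 log2 on control arrays (SD, n = 3) and 6.69 ± 0.17 on elicitor arrays (n = 9; exact permutation p = 0.0909). Control replicate 1 was at 7.28 and the other controls at 6.80, and without it the difference was 0.11 rather than 0.27. Hybridization controls averaged 8.97 ± 0.20 and 8.82 ± 0.07 (exact permutation p = 0.05). The actin probe set difference between the 3' and 5' ends, a sign of RNA degradation, was 1.92 ± 0.34 on control and 1.86 ± 0.17 on elicitor arrays (exact permutation p = 0.645). For GAPDH it was 0.142 ± 0.079 on control arrays and 0.028 ± 0.022 on cellobiose arrays (exact permutation p = 0.1, the smallest possible), 0.144 ± 0.107 with chitin (p = 1) and 0.124 ± 0.048 with OGs (p = 0.9).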

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

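Spike-in scaling, ordinary t tests, response size and the alternatives on them were chosen after seeing the data. No named gene changed direction in any setting. No list did where it passed in the main fit or in the other setting. Turns of lists that passed in neither were not counted. Of 765 values of named genes under other settings 141 lost their call, as did 307 of 882 with a replicate or array left out. With bright probe sets alone, 0 differences were called between cellobiose and chitin, 1 between cellobiose and OGs and 19 between chitin and OGs. That setting removes 4 of 4, 5 of 10 and 6 of 24 of the calls, so it does not test whether background limits them. No detection calls were given, so ratios over dim control levels may be off by an unknown amount. Where a count moved, the cause was not tested.

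The replicate numbers were used as a block because the design text takes ratios per pair. Of 18 same-number pairs, 11 had deviations that correlated above 0.1. Those of replicate 1 ran from 0.30 to 0.59 and the others from -0.17 to 0.41, and 4 of 12 arrays correlated best with their own number. The second principal component, with 13.8% of the variance, set replicate 1 of every group apart. Its arrays lay at 19.9 to 32.3 and all others at -21.3 to -6.6. With no replicate block the counts were 1794 for cellobiose, 1841 for chitin and 854 for OGs, and 5, 19 and 32 for cellobiose against chitin, cellobiose against OGs and chitin against OGs. Phenylpropanoid synthesis then passed with OGs (adjusted p = 0.0397), and no other list call changed. Replicate as a random block gave 19 for cellobiose against OGs.

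With a 2-fold minimum the counts were 791 for cellobiose, 855 for chitin and 509 for OGs. Mean ratios of 2-fold with no test gave 946 for cellobiose and 931 for chitin, and 114, 131 and 207 between elicitors. Fitting only the 2 groups gave 146 for OGs against control and 0, 0 and 0 between elicitors. Quantile normalization gave 3 for cellobiose against OGs, all higher with cellobiose. Ordinary t tests, which pool no spread over probe sets, gave 1006 for cellobiose, 1111 for chitin and 79 for OGs, and 0, 0 and 1 between elicitors. They kept 17 of 24, 21 of 26 and 4 of 24 named genes against control, and none of the named differences between elicitors. After spike-in scaling they gave 938, 730 and 296, and 0, 0 and 0 between elicitors; the median of all probe sets was then 0.34 log2 for cellobiose, 0.17 for chitin and 0.20 for OGs, and the share of calls that were higher went from 62.8% to 99.4%, 66.9% to 97.9% and 88.6% to 100%. The scaling added the same amount to every change of a comparison and raised the median residual SD from 0.134 to 0.256, so calls on falls ended through a smaller fold and a wider spread. Without control replicate 1 those medians were 0.17, 0.00 and 0.03, and scaled calls were 330 higher and 4 lower for cellobiose, 225 and 4 for chitin and 4 and 0 for OGs, against 437 and 133, 496 and 139, and 101 and 10 unscaled. Without control replicate 3 unscaled ordinary t tests gave 0 calls with each elicitor. They also gave 0 for cellobiose without cellobiose replicate 1, and 0 for OGs without control replicate 2, OGs replicate 1 or OGs replicate 3.

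With replicates or arrays left out, counts ranged from 651 to 1808 for cellobiose, 746 to 1861 for chitin and 47 to 1369 for OGs, and from 0 to 90, 0 to 86 and 2 to 105 between elicitors in the order above. Without replicate 2 the 90 were 1 higher and 89 lower with cellobiose than chitin. The lowest came without replicate 1, replicate 2 and replicate 3 against control. Correlations ranged from 0.88 to 0.922 for cellobiose and chitin, 0.862 to 0.912 for cellobiose and OGs and 0.841 to 0.919 for chitin and OGs, and with bright probe sets the first was 0.948. The difference in response size ranged from 0.148 to 0.402 between chitin and OGs, 0.134 to 0.415 between cellobiose and OGs and -0.185 to 0.0277 between cellobiose and chitin.

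With an estimated correlation the adjusted p was 0.0505 for immunity markers and calcium genes with all elicitors, 0.0673, 0.0755 and 0.0505 for pectin genes with cellobiose, chitin and OGs, and 0.0846 for phenylpropanoid synthesis with cellobiose, which also missed with bright genes only (0.0556) and with ordinary t statistics (0.0532, and 0.0604 after spike-in scaling). With OGs phenylpropanoid synthesis passed in fry (0.027) and after median centring (0.0485), and ranged from 0.00843 to 0.148 with a replicate left out. The reference genes passed in fry, which does not compare them with other genes, at 0.00613, 3.41e-04 and 0.00966. WRKY30 was not analysed here, so it has no alternatives.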

Other observations

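Gene families formed from symbols, neighbouring genes and all tests of explanations in this part were chosen after the results were seen, except the test on other BGLU genes and the counts over splits of the arrays. Among 68 families with at least 5 measured genes, 12 of 204 tests passed camera at the preset correlation and 0 passed with an estimated correlation. Relative to other genes the ATG family, mostly ATG8 genes of autophagy, shifted down with cellobiose, chitin and OGs (camera adjusted p = 1.37e-04, 1.37e-04 and 0.00137), with medians of -0.48, -0.48 and -0.30 log2. Of its 11 measured genes, 6 fell with cellobiose and 5 with chitin, and 0 passed with OGs. All except ATG3 and AT5G66930 are ATG8 genes, for the ubiquitin-like protein that coats autophagosomes. ATG3 and AT5G66930 passed with no elicitor, so every call was on an ATG8 gene and autophagy genes at large were not shown to fall. ATG8G fell by 0.72 ± 0.10 log2 (SE) with cellobiose and by 0.55 ± 0.10 with chitin, and ATG8E by 0.51 ± 0.12 and 0.61 ± 0.12. With ordinary t tests 2 fell with cellobiose and 2 with chitin. After scaling to the poly-A spike-ins none passed and the medians were -0.10, -0.27 and -0.07. Camera at the preset correlation still put the family lower relative to other genes (adjusted p = 6.58e-07, 1.44e-05 and 6.28e-04). The scaling adds the same amount to every gene's change, so this adds no support. AT5G66390, a peroxidase gene, rose by 0.68 ± 0.11 log2 with cellobiose and was 0.94 ± 0.11 higher with cellobiose than with OGs (adjusted p = 0.0489). The call on that difference was lost when any cellobiose array or OGs replicate 1 or 2 was left out, and with ordinary t tests.

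Genes known only by locus were among the largest shared rises. AT3G02840 rose by 7.21 ± 0.42 log2 (SE) with chitin and 5.10 ± 0.42 with OGs, AT5G28610 by 5.87 ± 0.44 and 4.73 ± 0.44, and AT5G52750 by 5.74 ± 0.45 and 4.13 ± 0.45. AT2G35585, AT4G16750 and AT3G52070 were among the shared falls, by 1.74 ± 0.29, 1.56 ± 0.28 and 1.41 ± 0.20 with chitin. Genes that rose lay next to each other along the chromosomes more often than in 1000 shuffles of the calls over measured genes. Neighbouring pairs numbered 46 with cellobiose, 59 with chitin and 25 with OGs, against means of 18.5, 21.4 and 8.76 (permutation p = 0.001 each, the smallest possible). Falls had 15, 19 and 2 pairs against 13.3, 12.1 and 0.46 (permutation p = 0.35, 0.037 and 0.081). These 6 tests, adjusted for none of the others, do not say what neighbours share.

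The OGs response was smaller than the others in mean size. Chance was not excluded for either difference (exact permutation p = 0.1 for chitin, the smallest possible, and 0.3 for cellobiose). OGs replicate 2 did not make up the whole of the observed difference from chitin. Without it the response to OGs stayed 0.186 log2 lower, with both remaining OGs arrays (at most 1.05) below every chitin array (at least 1.13). With so few arrays chance is not excluded for what was left, so no cause is concluded. For cellobiose the difference without OGs replicate 2 was 0.134, and the arrays overlapped (1.08 against 1.01), so that array as the whole cause cannot be told apart. A compressed range on the OGs arrays could not be judged from the deposited values. The authors' quantile normalization makes the ranges of arrays alike, so their ratio cannot test this. The interquartile range on OGs arrays was 1.01 times that on chitin arrays (lowest ratio of single arrays 0.994), while the response was 0.745 times as large (highest ratio 0.93). For cellobiose these were 0.997 and 0.778, and the array responses overlapped (highest ratio 1.08). Another quantile normalization left differences of 0.288 and 0.237, but the authors' own had already made the ranges alike. Compression of the scanner signal before it stays open, as scanner files were not used. No biological explanation was tested.

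BGLU27 with cellobiose, and AT3G12910 and AT2G36440 with chitin, differed between elicitors. These genes were chosen for that difference, so how well their arrays separate does not test it. For BGLU27, signal from a related beta-glucosidase could not be told apart, as 0 of 21 other BGLU probe sets was at least 1 log2 higher with cellobiose than with both others, but unnamed members were not searched. The largest differences were 0.38 from chitin (BGLU15) and 0.52 from OGs (BGLU32). No biological explanation was tested.

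The responses to the 3 elicitors resembled each other. Noise of single probe sets in the shared control arrays is argued against as the whole source. The lowest covariance of fold changes, 0.196, exceeded the highest simulated value of 0.013. A systematic difference of the control arrays would enter all 3 comparisons. It was not simulated, so it cannot be told apart from a shared response. The RNA samples had also been screened on WRKY30, and what that does to the likeness was not tested. No biological explanation was tested.

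With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. For each of the 6 comparisons 1 of the 10 splits, the real one, gave as many calls. Some splits put both arrays of a replicate number in the same group, although the replicate block was kept, so the splits are not alike. The real and highest other counts were 1966 and 85 for cellobiose, 2002 and 0 for chitin and 924 and 0 for OGs against control. Between elicitors they were 4 and 0 for cellobiose and chitin, 10 and 0 for cellobiose and OGs, and 24 and 1 for chitin and OGs. Among splits that parted every pair, the highest other count was 85 for cellobiose against control and 0 in the other comparisons. No conclusion is drawn from these counts.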
